A study of Mus musculus with 24 samples.

How the data were processed

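Total RNA was sequenced from 24 libraries of mouse embryonic stem cells, 2 for each of 12 groups defined by the Ctcf transgene (wild type or 1 of 9 substitutions) and the treatment (none, IAA, or IAA with doxycycline). Per the labels, libraries were stranded and depleted of ribosomal RNA from 500 ng of RNA, read as 150 bp pairs, and planned at 100 M (reads in units of 1000 × 1000). The labels do not say whether the 2 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

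Gene-level signal was deposited as normalized counts in 1 table of 22 libraries and a separate table of the 2 untreated libraries, and as TPM (transcripts scaled by gene length to a constant sum per library) in a matching pair of tables. Per the submitters' processing notes, the authors used Trim Galore, STAR and DESeq2 with the mm10 build. Tool versions, the read counter, the annotation and the strand setting are not given in the sources used here. The deposited normalized counts are gene counts divided by 1 size factor per library. In each library 100% of the values were whole multiples of 1 step within 0.001 normalized counts, so whole reads could be recovered. The 22 size factors equal the median-of-ratios factors that DESeq2 gives for those 22 libraries. Those of the untreated libraries equal neither the factors of that pair alone nor those of all 24, so the untreated table was scaled separately. TPM ratios were therefore used across the tables, with edgeR on recovered reads as an alternative. Recovered reads divided by the deposited TPM give 1 length per gene up to a factor per library. The tables held 0 columns of samples from outside the series.

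The tables list 55291 gene symbols, of which 53180 were found once in GENCODE M21 and given its mm10 coordinates. Because the strand setting is unknown, values of genes that overlap on opposite strands are uncertain. Values of near-identical families (Xlr genes, Zscan4 and other 2-cell-like state genes, histone genes, clustered protocadherins) are uncertain too, since the treatment of reads that map to several places is unknown. The substituted residues were placed on the mouse Ctcf coding sequence of the mm10 genome.

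The tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Normalized counts were taken as log2(count + 1), and genes with a mean of at least 10 over the 22 libraries were kept (18713 genes). A linear model with 1 coefficient per group was fitted to all 22 libraries with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), leaving 11 residual and 8.13 prior degrees of freedom. Two-sided moderated tests were adjusted by Benjamini-Hochberg within each of 11 comparisons, and genes with an adjusted p under 0.05 were called. Comparisons were WT IAA with WT ID, each mutant with WT ID, and R377C with R377H. Errors after log2 fold changes are standard errors, and those after counts are standard deviations. Untreated cells were compared with WT ID by log2 ratios of mean TPM (+ 0.1), and genes at least 2-fold apart with no overlap of the 2 + 2 libraries were counted.

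Tests were tried on data simulated with the depths, gene means and spread of all 22 libraries. In R339Q alone, 50 of 18713 genes were changed by each of 4 fold sizes. Far more genes (4018) were called in the real R339Q comparison, so recovery there was not measured. The limma test recovered 38% of those changed 1.5-fold, 64% of those changed 2-fold, 88% of those changed 3-fold and 92% of those changed 4-fold, with 4 false calls among 145. edgeR 4.0.16 recovered 36%, 64%, 86% and 88% with 3 false calls among 140, and DESeq2 1.42.0 recovered 42%, 64%, 86% and 88% with 8 among 148. In comparisons of unchanged groups DESeq2 made 17 calls, and limma and edgeR made 0.

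The 27 gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over all 297 list tests, and with an estimated correlation beside it. Of 746 listed genes 743 were matched, 53 of them through a synonym. Lists covered core and naive pluripotency, formative and primed pluripotency, 2-cell-like state, germline, primitive endoderm, mesendoderm, neural ectoderm, trophectoderm, fibroblast, Hox, imprinted and clustered protocadherin genes. They also covered loop extrusion genes and CTCF partners, p53 targets, cell cycle, replication-dependent histones, integrated stress response, heat shock and unfolded protein, glycolysis and hypoxia, and nuclear and mitochondrially encoded respiratory genes. Cholesterol synthesis, Wnt targets, immediate early, interferon response, aryl hydrocarbon receptor and small structural RNA lists completed the set.

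Genes are named by rule. In WT IAA these were the 12 largest increases and the 12 largest decreases among called genes with a mean of at least 50, no overlap between the libraries compared, and a symbol that is not a model or clone name. In every other tested comparison they were the 5 largest per direction by the same limits. From each list that was called, or had at least 3 called members, up to 4 called members with the largest changes were eligible, and Ctcf was eligible everywhere. Members of the pluripotency, loop extrusion and protocadherin lists were eligible in any comparison. For genes changed in several mutants the 10 called the same way in most mutants were named per direction. A gene selected by this rule is not reported here.

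Overlap between each mutant and WT IAA was counted per direction beside n1 × n2 / N for independent lists. Covariances were set beside 100 simulated draws of unchanged groups against the same WT ID libraries, because both comparisons share them. The median log2 fold change of genes with a mean of at least 100 was computed per chromosome, and chromosomes more than 0.15 from the median over all chromosomes were called shifted.

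Alternatives were a pseudocount of 5, no low-count filter (39578 genes), quantile normalization, TPM in place of normalized counts, only the groups compared, replicate number as a block, edgeR and DESeq2 on recovered reads, adjustment over all comparisons jointly, and leaving out each library. Alternatives chosen after seeing the data were the counts without shifted chromosomes, values centred on the running median of 101 neighbouring genes along each chromosome, several mutants against WT IAA, every alternative for genes changed in several mutants, and WT IAA and the mutants against separate WT ID libraries. Leaving out libraries for gene lists, named genes, overlaps and chromosome shifts was also chosen then. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.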

Results

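Total RNA was sequenced from mouse embryonic stem cells of the E14Tg2a line in which the endogenous CTCF protein carries an auxin-inducible degron. CTCF is the zinc finger protein that binds insulator sites and halts loop extrusion by cohesin. Indole-3-acetic acid (IAA, an auxin) triggers degradation of the tagged protein, and doxycycline switches on a Ctcf transgene that is wild type (WT) or carries 1 of 9 missense substitutions. The 24 libraries formed 12 groups of 2. The WT transgene line was left untreated, treated with IAA alone (WT IAA), or treated with IAA and doxycycline (WT ID). Each of the 9 mutant lines was treated with IAA and doxycycline (R339Q ID to H455R ID). IAA was used at 500 µM and doxycycline at 1 µg/ml for 2 days.

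Recovered reads per library ranged from 27.8 M to 77.1 M (M, reads in units of 1000 × 1000). Replicates 1 and 2 held 31.0 and 36.9 M in untreated cells, 47.3 and 35.0 M in WT IAA and 57.5 and 42.9 M in WT ID. The mutant libraries held 44.2 and 34.7 in R339Q and 77.1 and 35.4 in R342C. They held 38.9 and 32.6 M in S354F, 44.5 and 39.0 in K365T, 64.7 and 40.9 in R377C and 37.2 and 41.5 in R377H. The remaining pairs held 27.8 and 52.3 M in Q418R, 46.0 and 50.4 in R448Q and 36.0 and 49.2 in H455R. The 2 libraries of each group differed by more than sampling noise (chi-square per gene 5.83 to 34.8), so none was counted as a repeat of another. Mitochondrially encoded RNA took 1.62% and 1.92% of the reads in the 2 WT ID libraries and 1.22% (K365T replicate 2) to 3.38% (R448Q replicate 2) over all 24 libraries.

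The 9 substitutions lie in or beside the zinc fingers of the 736-residue mouse protein, as placed here on the mm10 gene (Ctcf, ENSMUSG00000005698.15, chromosome 8, 105636568 to 105682922, plus strand). R339Q (codon 105666721 to 105666723), R342C (105666730 to 105666732) and S354F (105666766 to 105666768) are coded in exon 5. The first pair lies within zinc finger 3 and S354F within finger 4. K365T (finger 4, 105670237 to 105670239) and both R377H and R377C (between the motifs of fingers 4 and 5, 105670273 to 105670275) are coded in exon 6. Q418R (finger 6, 105671335 to 105671337) and R448Q (finger 7, 105671425 to 105671427) lie in exon 7. H455R (finger 7, 105674874 to 105674876) lies in exon 8.

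Ctcf RNA, which does not report the degraded protein, was measured first. The sources used here do not say whether transgene reads were counted with those of the endogenous gene, so these values may or may not include the transgene. The normalized count was 10196 ± 315 (mean ± SD, n = 2) in WT ID and 9180 ± 95.6 in WT IAA. Their log2 fold change of −0.15 ± 0.06 (SE) did not pass (limma adjusted p = 0.0922). Among the mutants, Ctcf rose in R448Q to 20431 ± 326 (log2 fold change 1.0 ± 0.06, adjusted p = 2.90e-10) and in H455R to 16851 ± 141 (0.73 ± 0.06, adjusted p = 1.48e-07). It was lower in R342C (−0.25 ± 0.06, adjusted p = 0.00697) and higher in Q418R (0.22 ± 0.06, adjusted p = 0.0121) and K365T (0.18 ± 0.06, adjusted p = 0.0291). These smaller calls were lost when 1 library was left out (R342C adjusted p up to 0.0813 without R342C ID replicate 1 or without WT ID replicate 2, Q418R adjusted p up to 0.113 without Q418R ID replicate 2 or without WT ID replicate 1, and K365T adjusted p up to 0.184 without K365T ID replicate 1 or without WT ID replicate 1 or without WT ID replicate 2). Values in R339Q (−0.0032 ± 0.06), S354F (0.03 ± 0.06), R377C (0.17 ± 0.06) and R377H (0.05 ± 0.06) did not pass. Chromosome 8, which carries Ctcf, was higher as a whole in R448Q, H455R and K365T (below). After centring along the chromosome, an alternative chosen after seeing the data, the log2 fold change was 0.55 in R448Q, and the H455R call ended at 0.15. The centred values of K365T (−0.00788) and Q418R (0.17) did not pass either. Untreated cells, scaled in a separate table, gave 8685 ± 446.

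**Figure D1:**
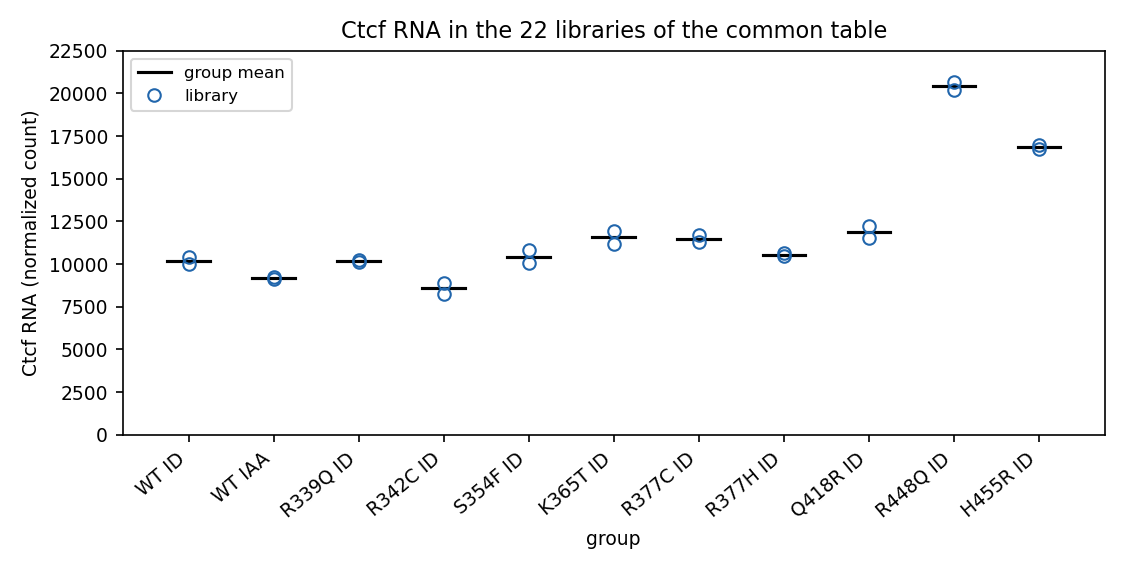
Ctcf RNA in each of the 22 libraries of the common table, as normalized counts by group, with circles for libraries and bars for group means. The R448Q mean (20431) and the H455R mean (16851) lie above the WT ID mean (10196).

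Loss of CTCF without a transgene was examined by setting WT IAA against WT ID, the same line with IAA in both arms and doxycycline in ID only. Genes of the integrated stress response, which act when translation initiation is slowed, fell together. Chac1, a glutathione-degrading enzyme (chromosome 2, 119351229 to 119354381), went from 1535 ± 82.2 to 231 ± 32.8 (log2 fold change −2.74 ± 0.15, adjusted p = 7.63e-10). The secreted hormone Stc2 (−2.02 ± 0.22), the pseudokinase Trib3 (−1.94 ± 0.19) and the stress-induced Nupr1 (−1.86 ± 0.19) fell with it. Of the 28 measured genes of this list 0 rose, 25 fell and 3 did not pass the test, or 0 up and 26 down adjusted over the list alone (camera adjusted p = 7.85e-19, and adjusted p = 0.498 with an estimated correlation). Genes of the 2-cell-like state, a transient state of cultures resembling the early embryo, rose in 18 of 24 cases and fell in 0 (20 up and 0 down adjusted over the list alone, camera adjusted p = 7.45e-08, and adjusted p = 0.579 with an estimated correlation). Examples were Zscan4e (2.81 ± 0.66) and Gm4340 (3.67 ± 0.70), members of families whose near-identical copies share reads. Of 28 p53 targets 17 rose, 1 fell and 10 did not pass the test (20 up and 1 down adjusted over the list alone, camera adjusted p = 3.67e-07, and adjusted p = 0.633 with an estimated correlation). Examples were Perp, a membrane protein of apoptosis (1.16 ± 0.19), and the kinase gene Plk2 (1.01 ± 0.16). Cholesterol synthesis genes gave 9 decreases and 0 increases among 23 (0 up and 13 down adjusted over the list alone, camera adjusted p = 1.83e-05, and adjusted p = 0.633 with an estimated correlation). Examples were the sterol enzymes Tm7sf2 (−1.12 ± 0.15), Cyp51 (−0.73 ± 0.10) and Msmo1 (−0.63 ± 0.08). Clustered protocadherins, adhesion genes with alternative promoters bound by CTCF, fell in 10 of 16 cases with 0 increases (0 up and 10 down adjusted over the list alone, camera adjusted p = 2.10e-05, and adjusted p = 0.486 with an estimated correlation). Pcdhgb8 changed by −2.59 ± 0.43 and Pcdhga11 by −2.52 ± 0.39, at mean counts of 4.84 and 6.91 in WT IAA.

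Among single genes in WT IAA, the largest of 12 named increases were Nlrp4c of an oocyte-expressed family (chromosome 7, 6045161 to 6105150, log2 fold change 3.63 ± 0.39, adjusted p = 3.72e-06), the lectin Siglec1 (2.81 ± 0.37), Rbfaos (2.77 ± 0.42), Tex19.2 (2.68 ± 0.29), the protease Tmprss6 (2.58 ± 0.33) and the neuropeptide precursor Vgf (2.43 ± 0.26). Following these were Khdc1a, Oas1e, Rimbp2, Krt19, Id3 and the angiopoietin receptor Tek (2.13 ± 0.23). Of 12 named decreases the largest were the cytokine receptor Il9r (chromosome 11, 32187541 to 32200279, log2 fold change −5.45 ± 0.42, adjusted p = 5.88e-08), Fgg, Chac1, the noncoding Snhg17 (−2.72 ± 0.21), the sodium channel Scn3a (−2.69 ± 0.26), the oxidase Duox1 (−2.55 ± 0.21), and next came Snx19, Entpd3, Zfr2, Det1, Tex261 (−2.2 ± 0.15) and B4galnt2. Of genes outside those sets, the growth factor Vegfa fell (−1.03 ± 0.09). The developmental pluripotency genes Dppa2 (0.96 ± 0.09) and Dppa3 (1.45 ± 0.30) rose, and the chaperone Hspa8 rose (0.88 ± 0.14). The core factors Pou5f1 (−0.06 ± 0.08) and Sox2 (0.06 ± 0.08) did not pass, and Nanog rose (0.34 ± 0.08; adjusted p up to 0.0704 without WT IAA replicate 2 or without WT ID replicate 1). Markers of other lineages moved singly, with the transcription factors Gata6 (1.28 ± 0.26) and Gata2 (−1.55 ± 0.25) and the collagen Col1a1 (1.45 ± 0.23) as examples. In all, 3868 of 18713 genes were called (1864 up, 2004 down). By at least 2-fold 492 rose and 329 fell. The split was 1739 up and 1555 down on TPM, 2050 up and 2017 down after quantile normalization and 2019 up and 1905 down with edgeR. Leaving out 1 library, which leaves its group with a lone sample assumed to vary like the others, gave 2537 without WT IAA replicate 1, 1804 without WT IAA replicate 2, 2122 without WT ID replicate 1 and 2028 without WT ID replicate 2.

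**Figure D2:**
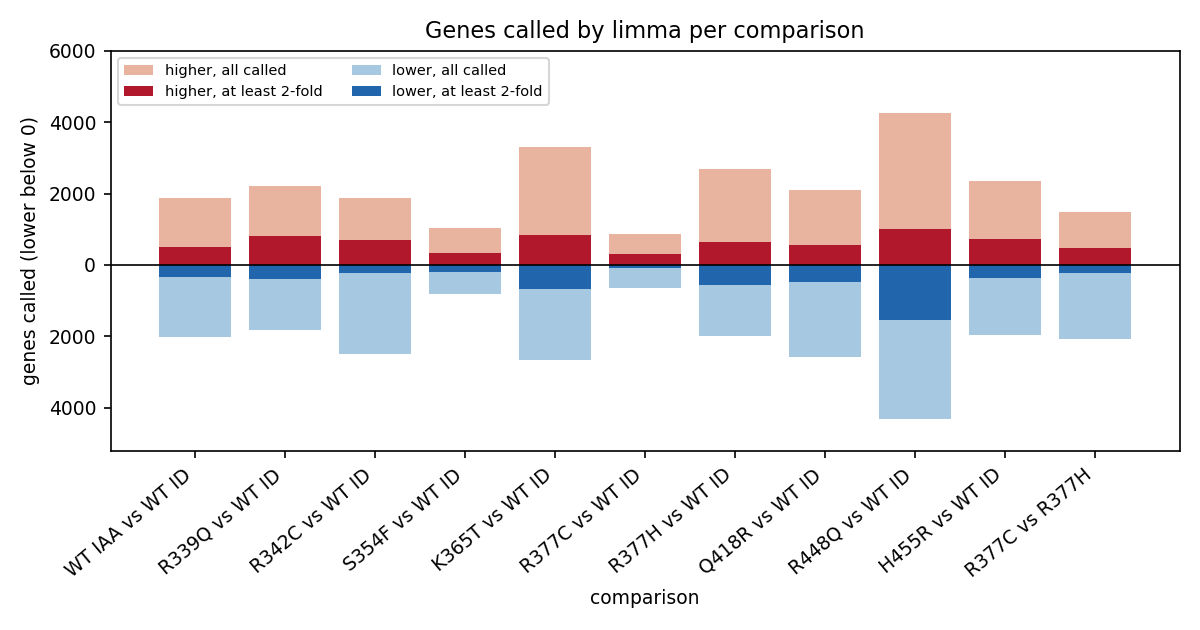
Genes called by limma in each comparison, with increases above 0 and decreases below 0 and the darker part of each bar showing those changed at least 2-fold. R448Q had the most calls (8578) and R377C the fewest (1514).

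Whole chromosomes stood apart in 5 of the 9 mutant lines, and this bears on every count for them. The median log2 fold change of a chromosome relative to all chromosomes was 0.56 for chromosome 11 in R377H. In R448Q it was 0.58, 0.56, 0.53 and 0.22 for chromosomes 1, 3, 8 and 11. Chromosome 8 in H455R gave 0.5, and chromosomes 6 and 1 in Q418R −0.49 and 0.22. K365T gave 0.41, 0.35 and 0.22 for chromosomes 11, 1 and 8. No chromosome moved by more than 0.15 in WT IAA, R339Q, R342C, S354F or R377C. That limit sets the number of lines, since smaller shifts also lay outside all 1000 random gene lists of their size. These were 9 chromosomes in R377C (at most 0.13, on 8), 3 in WT IAA (0.05, on 1), 2 in R342C (−0.07, on X), 1 in R339Q (0.095, on 11) and 0 in S354F. Parts of chromosomes may still have shifted, as near Pds5b in R342C and S354F (below). Genes on the shifted chromosomes made up 27.2% of the calls in K365T, 18.5% in R377H, 18.6% in Q418R, 29.3% in R448Q and 12.4% in H455R, and 18.5%, 7.35%, 11.3%, 23.4% and 5.02% of the genes tested. Counts without those chromosomes, an alternative chosen after seeing the data, were 4355, 3825, 3807, 6065 and 3784.

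**Figure D3:**
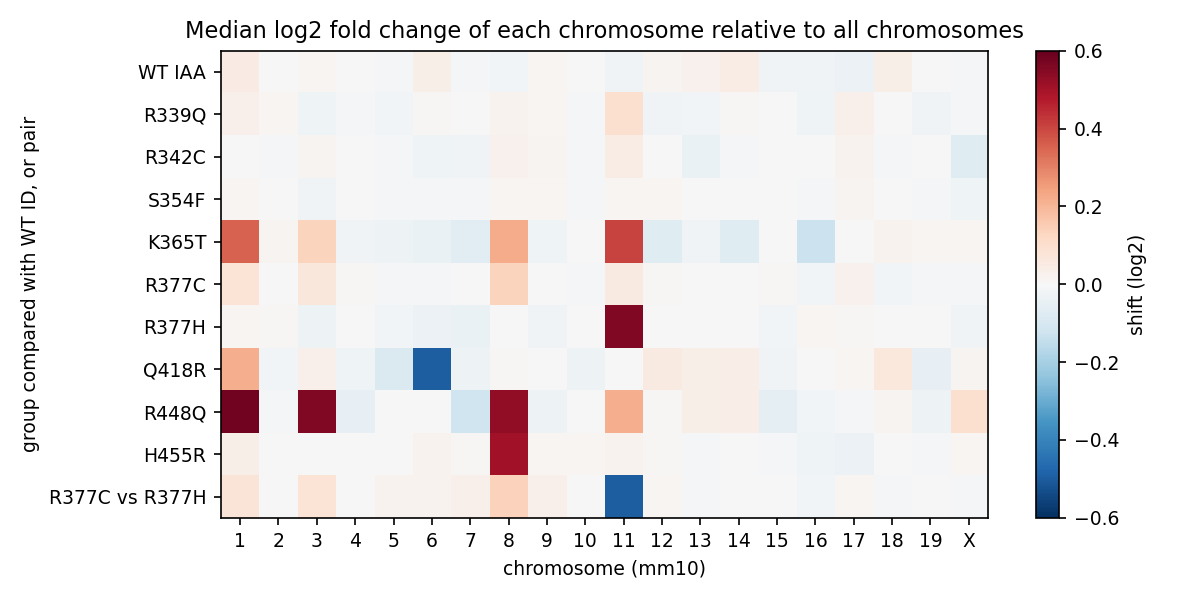
Median log2 fold change of the genes of each chromosome relative to all chromosomes, for each comparison, from −0.6 (blue) to 0.6 (red). The strongest colours are chromosomes 1, 3 and 8 in R448Q, 11 in R377H, 8 in H455R, 6 in Q418R and 11 in R377C against R377H.

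Each mutant was then compared with WT ID, which asks how cells kept on a substituted CTCF differ from cells kept on the wild-type transgene. Every mutant is a separate cell line, so line and substitution cannot be told apart in these comparisons.

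In R339Q the genes of the X-linked Xlr3, Xlr4 and Xlr5 cluster, whose near-identical copies share reads, fell most. Xlr3c (chromosome X, 73254540 to 73265390) dropped from 1603 ± 58.8 to 88.1 ± 0.117 (log2 fold change −4.17 ± 0.25, adjusted p = 2.44e-09), with Xlr5b (−4.48 ± 0.36), Xlr4c (−4.1 ± 0.38), Xlr5a (−3.76 ± 0.30) and Xlr4b (−3.57 ± 0.23) beside it. The paternally expressed imprinted genes Peg3 (−3.0 ± 0.19, adjusted p = 4.15e-09) and Usp29 (−1.88 ± 0.21), which share a domain, fell as well, as did the imprinted cell cycle regulator Plagl1 (−1.42 ± 0.08). The largest increases were the T cell co-receptor Cd4 (2.98 ± 0.23, adjusted p = 3.12e-08), Tek (2.8 ± 0.23), Tmem132d (2.73 ± 0.29), Tex19.2 (2.56 ± 0.29) and Oas1e (2.54 ± 0.28). Of 28 integrated stress response genes 0 rose, 17 fell and 11 did not pass the test (0 up and 18 down adjusted over the list alone, camera adjusted p = 1.85e-08, and adjusted p = 0.633 with an estimated correlation). Examples were Vldlr (−1.44 ± 0.21) and Chac1 (−1.34 ± 0.15). Cholesterol synthesis genes fell in 16 of 23 cases and rose in 0 (0 up and 17 down adjusted over the list alone, camera adjusted p = 7.59e-08, and adjusted p = 0.542 with an estimated correlation). Cyp51 was at −0.9 ± 0.10 and Dhcr7 at −0.67 ± 0.12. For 28 p53 targets the counts were 15 up and 0 down (16 up and 0 down adjusted over the list alone, camera adjusted p = 3.73e-06, and adjusted p = 0.652 with an estimated correlation). The death receptor Fas was at 1.88 ± 0.39 and Plk2 at 1.14 ± 0.16. Germline genes, silent in most somatic cells, rose in 14 and fell in 1 of 31 cases (16 up and 3 down adjusted over the list alone, camera adjusted p = 2.34e-04, and adjusted p = 0.633 with an estimated correlation). Examples were the testis bromodomain gene Brdt (2.0 ± 0.14) and Tex101 (1.93 ± 0.28). Primitive endoderm markers gave 5 up and 1 down of 12 (6 up and 1 down adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.458 with an estimated correlation). The laminin Lamb1 was at 1.66 ± 0.15. Cell cycle genes gave 1 up and 10 down of 34 (1 up and 10 down adjusted over the list alone, camera adjusted p = 0.0265, and adjusted p = 0.872 with an estimated correlation). That call was lost with adjusted p = 0.127 without R339Q ID replicate 2 and 0.0902 without WT ID replicate 2. In all 4018 genes were called (2202 up, 1816 down). By at least 2-fold 801 rose and 382 fell. Fewer libraries gave fewer calls, 1890 without R339Q ID replicate 1, 2362 without WT ID replicate 1 and 2449 without WT ID replicate 2.

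R342C showed the same cluster at the head of its decreases. Xlr5a fell from 239 ± 13 to 6.0 ± 1.35 (log2 fold change −5.11 ± 0.30, adjusted p = 7.92e-09). Next were Xlr5b (−4.96 ± 0.36), Xlr4c (−3.82 ± 0.38), Xlr3c (−3.65 ± 0.25) and Xlr4b (−3.31 ± 0.23). Its largest increases were Evc of the primary cilium (chromosome 5, 37289098 to 37336894, 2.33 ± 0.35, adjusted p = 1.58e-04), Mlph (2.19 ± 0.40), the major histocompatibility gene H2-Q7 (2.02 ± 0.25), the piRNA pathway gene Tdrd1 (2.02 ± 0.33) and the testis histone gene H2ac1 (2.01 ± 0.24). Of 28 integrated stress response genes 4 rose, 0 fell and 24 did not pass the test, with a median of 0.27 (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.00614, and adjusted p = 0.872 with an estimated correlation). Cell cycle genes fell in 19 of 34 cases and rose in 1 (1 up and 23 down adjusted over the list alone, camera adjusted p = 5.79e-06, and adjusted p = 0.633 with an estimated correlation). The mitotic kinase Plk1 was at −0.46 ± 0.09 and the replication helicase subunit Mcm5 at −0.39 ± 0.07 against the cyclin Ccnd2 at 1.61 ± 0.22. Nuclear genes of oxidative phosphorylation gave 11 decreases and 0 increases of 44 (0 up and 18 down adjusted over the list alone, camera adjusted p = 5.90e-05, and adjusted p = 0.838 with an estimated correlation). Among the decreases was the ATP synthase subunit Atp5g3 (−0.54 ± 0.08). Loop extrusion genes and CTCF partners fell in 11 of 23 cases and rose in 0 (0 up and 13 down adjusted over the list alone, camera adjusted p = 2.35e-04, and adjusted p = 0.542 with an estimated correlation), led by the cohesin regulator Pds5b (−0.7 ± 0.07, adjusted p = 1.01e-06), whose call ended after centring along chromosomes (−0.11). Of 28 p53 targets 17 rose and 1 fell (19 up and 1 down adjusted over the list alone, camera adjusted p = 2.53e-06, and adjusted p = 0.652 with an estimated correlation). Fas was at 2.32 ± 0.39. Of 31 germline genes 14 rose and 0 fell (14 up and 0 down adjusted over the list alone, camera adjusted p = 3.44e-05, and adjusted p = 0.633 with an estimated correlation). Tdrkh was at 1.92 ± 0.24. Primitive endoderm markers rose in 7 of 12 cases and fell in 0 (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.00104, and adjusted p = 0.226 with an estimated correlation). Among them was the transcription factor Gata4 (1.29 ± 0.14). Cholesterol synthesis genes, with 6 down and 1 up of 23 (1 up and 7 down adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 0.828 with an estimated correlation), lost the call with adjusted p = 0.122 without R342C ID replicate 2 and 0.139 without WT ID replicate 1. The chaperones Hsph1 (−1.15 ± 0.11) and Hspb1 (−0.76 ± 0.11) and the Wnt target Sp5 (−2.02 ± 0.24) also fell. The 4365 called genes split into 1871 up and 2494 down (696 and 232 by at least 2-fold). The split was 2264 up and 963 down on TPM, 1922 up and 1849 down after quantile normalization, 2308 up and 2165 down with edgeR and 1487 up and 1152 down with only these groups fitted. The excess of decreases grew without R342C ID replicate 2. It nearly closed without R342C ID replicate 1, the deepest library (77.1 M), and without either WT ID library. The TPM scale moved the median of all genes by 0.100. After quantile normalization the list medians went from −0.2 to −0.07 for loop extrusion genes, −0.2 to −0.1 for oxidative phosphorylation, −0.18 to −0.06 for cholesterol synthesis and −0.25 to −0.15 for cell cycle genes. Without 1 library the count was 2248 without R342C ID replicate 1, 2572 without WT ID replicate 1 and 2003 without WT ID replicate 2.

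S354F lowered the maternally expressed noncoding RNAs of the imprinted Dlk1-Dio3 region on chromosome 12. Rian (chromosome 12, 109603940 to 109661716) fell from 13870 ± 839 to 1334 ± 371 (log2 fold change −3.4 ± 0.18, adjusted p = 1.82e-09), and Meg3 (−3.4 ± 0.26), Mirg (−3.24 ± 0.28) and Mir433 (−3.88 ± 0.43) fell with it. Xlr5a (−3.29 ± 0.30) completed the 5 largest decreases. Increases were led by the cardiac myosin gene Myh6 (2.09 ± 0.38, adjusted p = 0.00119), Myo7a (1.92 ± 0.28), Tex101 (1.84 ± 0.28), Rab17 (1.8 ± 0.26) and Evc (1.74 ± 0.35; adjusted p up to 0.0915 without S354F ID replicate 1 or without WT ID replicate 1). Germline genes rose in 13 of 31 cases and fell in 0 (16 up and 1 down adjusted over the list alone, camera adjusted p = 7.36e-07, and adjusted p = 0.529 with an estimated correlation). The 28 p53 targets gave 11 up and 1 down (13 up and 2 down adjusted over the list alone, camera adjusted p = 8.16e-05, and adjusted p = 0.744 with an estimated correlation). Ccng1 was at 0.59 ± 0.12. Primitive endoderm markers gave 3 up and 0 down of 12 (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.475 with an estimated correlation). Gata4 was at 1.29 ± 0.14 and Lamb1 at 1.19 ± 0.15. Further list calls were lost when 1 library was left out. These were cholesterol synthesis genes, with 4 of 23 down and 0 up (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.00124, and adjusted p = 0.689 with an estimated correlation; 0.0553 without WT ID replicate 1). Also lost were integrated stress response genes, with 4 of 28 down and 0 up (0 up and 9 down adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.857 with an estimated correlation; 0.209 without S354F ID replicate 2). Mitochondrially encoded mRNAs were up in 2 and down in 0 of 13 cases (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0112, and adjusted p = 0.838 with an estimated correlation; 0.0880 without S354F ID replicate 2). They took 2.62% and 2.92% of the reads in the 2 S354F libraries. Pds5b fell (−0.51 ± 0.07), with a log2 fold change of 0.0507 after centring along chromosomes. Of the 1834 genes called, 1028 were up and 806 down (328 and 204 by at least 2-fold), or 824 up and 527 down on TPM. Leaving out 1 library gave 1034 without S354F ID replicate 1, 1056 without S354F ID replicate 2, 908 without WT ID replicate 1 and 863 without WT ID replicate 2, with 515 up and 519 down without S354F ID replicate 1.

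In K365T, germline genes rose in 22 of 31 cases and fell in 2 (23 up and 2 down adjusted over the list alone, camera adjusted p = 7.36e-08, and adjusted p = 0.498 with an estimated correlation). Examples were the ankyrin repeat gene Asz1 (3.56 ± 0.51), the tubulin Tuba3b (3.04 ± 0.34) and the transcription factor Sohlh2 (2.34 ± 0.19). Tmem132d (chromosome 5, 127781630 to 128433077) went from 24.5 ± 0.570 to 445 ± 90.2 (log2 fold change 4.12 ± 0.29, adjusted p = 6.90e-09), ahead of Sh3bgrl (3.73 ± 0.26), Evc (3.56 ± 0.35), Igsf10 (3.41 ± 0.30) and the Polycomb-related Scml2 (3.41 ± 0.20). The largest decreases were the olfactory receptor Olfr459 (−5.06 ± 0.30, adjusted p = 2.18e-09), Pkhd1 (−4.66 ± 0.43), Nckap5 (−4.19 ± 0.41), Clca3b (−3.7 ± 0.24) and Arhgef38 (−3.22 ± 0.22). The imprinted Mirg (−2.2 ± 0.28), Peg3 (−2.17 ± 0.19), Meg3 (−1.79 ± 0.26) and Nnat (−1.74 ± 0.23) fell. Among the pluripotency and signalling genes, Lin28b (2.1 ± 0.16), Grhl2 (2.2 ± 0.14) and Ccnd1 (1.64 ± 0.10) rose, and the ERK feedback phosphatase Dusp6 fell (−1.7 ± 0.15). Nuclear oxidative phosphorylation genes were up in 20 and down in 0 of 44 cases (23 up and 0 down adjusted over the list alone, camera adjusted p = 0.00230, and adjusted p = 0.888 with an estimated correlation). The call did not hold at adjusted p = 0.193 without K365T ID replicate 2. Replication-dependent histone genes, a multicopy family, were up in 12 and down in 1 of 46 (9 up and 1 down adjusted over the list alone, camera adjusted p = 0.00889, and adjusted p = 0.896 with an estimated correlation). Leaving out libraries ended it, at adjusted p = 0.327 without K365T ID replicate 2 and 0.179 without WT ID replicate 1. There were 5979 calls (3313 up and 2666 down, 848 and 664 by at least 2-fold). The split became 2466 up and 3310 down on TPM and 1833 up and 2522 down without chromosomes 1, 8 and 11.

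R377C, the substitution with the fewest calls, raised germline genes in 15 of 31 cases and lowered 0 (19 up and 1 down adjusted over the list alone, camera adjusted p = 1.59e-10, and adjusted p = 0.430 with an estimated correlation). Brdt (chromosome 5, 107331159 to 107387058) went from 107 ± 12.8 to 464 ± 3.56 (log2 fold change 2.11 ± 0.14, adjusted p = 3.15e-08). The other top increases were the matrix protein Fbln2 (2.52 ± 0.30), Igsf10 (2.37 ± 0.30), H2ac1 (2.07 ± 0.24) and Tuba3b (2.02 ± 0.34). Decreases were led by Xlr5b (−3.44 ± 0.36, adjusted p = 4.71e-06), Xlr5a (−2.86 ± 0.30), Efhc2 (−2.73 ± 0.21), Xlr3c (−2.29 ± 0.25) and Pkhd1 (−2.26 ± 0.43; adjusted p up to 0.0578 without R377C ID replicate 2). The imprinted Peg10 rose (1.78 ± 0.29) and Peg3 fell (−1.48 ± 0.19). Genes of the 2-cell-like state were up in 8 and down in 0 of 24 cases (14 up and 0 down adjusted over the list alone, camera adjusted p = 6.09e-06, and adjusted p = 0.633 with an estimated correlation). The other list calls were each lost when 1 library was left out. p53 targets had 4 up and 0 down of 28 (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 0.872 with an estimated correlation; 0.15 without R377C ID replicate 2 and 0.386 without WT ID replicate 2). Primitive endoderm markers had 2 up and 0 down of 12 (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.0362, and adjusted p = 0.498 with an estimated correlation; 0.0569 without R377C ID replicate 1 and 0.0537 without R377C ID replicate 2 and 0.111 without WT ID replicate 2; 0.0506 after centring along chromosomes). Mitochondrially encoded mRNAs were up in 4 and down in 0 of 13 (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.838 with an estimated correlation; 0.0703 without R377C ID replicate 1), at 2.91% and 2.66% of the reads. The 1514 calls comprised 873 up and 641 down (318 and 98 by at least 2-fold), or 687 up and 383 down on TPM. Without 1 library they numbered 905 without R377C ID replicate 1, 582 without R377C ID replicate 2, 720 without WT ID replicate 1 and 729 without WT ID replicate 2.

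R377H, at the same arginine, lowered Hox genes, the homeobox genes of body axis patterning, in 14 of 31 cases and raised 2 (3 up and 18 down adjusted over the list alone, camera adjusted p = 1.03e-05, and adjusted p = 0.226 with an estimated correlation). Hoxa9 was at −2.04 ± 0.26 and Hoxa3 at −1.66 ± 0.20. The caudal homeobox gene Cdx2 fell with them (−2.5 ± 0.31). Germline genes rose in 20 and fell in 0 of 31 cases (23 up and 0 down adjusted over the list alone, camera adjusted p = 2.66e-07, and adjusted p = 0.498 with an estimated correlation), with Tuba3b (3.21 ± 0.34) and the synaptonemal complex gene Sycp1 (1.72 ± 0.23). Cholesterol synthesis genes fell in 16 and rose in 0 of 23 cases (1 up and 18 down adjusted over the list alone, camera adjusted p = 7.62e-07, and adjusted p = 0.579 with an estimated correlation). Msmo1 was at −0.71 ± 0.08. Protocadherins fell in 5 and rose in 0 of 16 (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.00629, and adjusted p = 0.633 with an estimated correlation). Pcdhga12 was at −1.09 ± 0.23. The single genes with the largest increases were Mlph (3.97 ± 0.40), the collagen Col6a3 (log2 fold change 3.84 ± 0.23, adjusted p = 1.20e-09), Wdfy4 (3.23 ± 0.35), Tuba3b and Scml2 (3.18 ± 0.20). Those with the largest decreases within the limits of the naming rule were Clca3b (chromosome 3, 144822623 to 144849357, from 607 ± 110.3 to 22 ± 2.74, −4.72 ± 0.24, adjusted p = 1.70e-10), Nckap5 (−4.48 ± 0.41), Pkhd1 (−4.17 ± 0.43), Olfr459 (−3.96 ± 0.30) and Slc44a5 (−3.45 ± 0.38). Imprinted Phlda2 (−2.22 ± 0.22) and Slc22a18 (−1.56 ± 0.22) fell and Mest rose (1.76 ± 0.18). The naive pluripotency gene Dppa3 rose (2.67 ± 0.30) and the smooth muscle actin Acta2 fell (−4.51 ± 0.56). Calls numbered 4696 (2696 up and 2000 down, 637 and 553 by at least 2-fold), or 1887 up and 2788 down on TPM and 1840 up and 1985 down without chromosome 11. Leaving out 1 library gave 3016 without R377H ID replicate 2 and 3071 without WT ID replicate 1.

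Q418R also lowered Hox genes, in 14 of 31 cases with 0 increases (0 up and 19 down adjusted over the list alone, camera adjusted p = 4.93e-06, and adjusted p = 0.226 with an estimated correlation), led by Hoxd13 (−2.09 ± 0.24) and Hoxd9 (−1.96 ± 0.16). Wnt targets rose in 10 and fell in 0 of 17 cases (11 up and 0 down adjusted over the list alone, camera adjusted p = 0.00284, and adjusted p = 0.551 with an estimated correlation), with the transcription factor Lef1 (2.68 ± 0.30), Sp5 (1.38 ± 0.24) and the Wnt antagonist Dkk1 (1.24 ± 0.23). The primed-state factor Otx2 (−2.36 ± 0.22), the ETS factor Etv4 (−2.15 ± 0.12) and the organizer gene Gsc (−1.5 ± 0.13) fell. Cholesterol synthesis genes fell in 11 and rose in 2 of 23 cases (2 up and 14 down adjusted over the list alone, camera adjusted p = 9.98e-04, and adjusted p = 0.687 with an estimated correlation). Cyp51 was at −1.04 ± 0.10 and Insig1 at −0.9 ± 0.09. Peg3 fell from 4037 ± 1413 to 508 ± 0.112 (chromosome 7, 6703892 to 6730431, log2 fold change −2.94 ± 0.19, adjusted p = 3.02e-09). Beside it stood Olfr459 (−3.17 ± 0.30, on the lowered chromosome 6), Mir142hg (−3.06 ± 0.43), the water channel Aqp8 (−2.82 ± 0.32) and Nat8l (−2.82 ± 0.21). The largest increases were Igsf10 (3.16 ± 0.30, adjusted p = 3.84e-07), Khdc1c (3.08 ± 0.47, on chromosome 1), the prohormone-processing enzyme Cpe (2.98 ± 0.24), Epdr1 (2.68 ± 0.24) and the pseudogene Mid1-ps1 (3.09 ± 1.04; adjusted p up to 0.357 without Q418R ID replicate 2 or without WT ID replicate 1 or without WT ID replicate 2). Genes of the 2-cell-like state were up in 11 and down in 2 of 24 (15 up and 2 down adjusted over the list alone, camera adjusted p = 0.00142, and adjusted p = 0.770 with an estimated correlation; 0.122 without Q418R ID replicate 2). p53 targets were up in 9 and down in 0 of 28 (10 up and 1 down adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.876 with an estimated correlation; 0.0556 without Q418R ID replicate 2 and 0.182 without WT ID replicate 2). Mitochondrially encoded mRNAs were up in 5 and down in 0 of 13 (5 up and 0 down adjusted over the list alone, camera adjusted p = 0.0258, and adjusted p = 0.857 with an estimated correlation; 0.0666 without Q418R ID replicate 1 and 0.0572 without WT ID replicate 1), at 3.23% and 2.60% of the reads. In all 4677 genes were called, 2088 up and 2589 down (562 and 482 by at least 2-fold), or 1217 up and 3416 down on TPM. With 1 library fewer they were 3010 without Q418R ID replicate 1, 2872 without WT ID replicate 1 and 3039 without WT ID replicate 2.

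R448Q, the line with the most shifted chromosomes, lowered neighbouring genes of an imprinted domain on chromosome 7. Phlda2 (chromosome 7, 143501545 to 143503150) fell from 401 ± 33.7 to 28.3 ± 5.75 (log2 fold change −3.79 ± 0.22, adjusted p = 2.07e-10), with Slc22a18 (−3.59 ± 0.22), the trophoblast factor Ascl2 (−3.0 ± 0.34) and Tspan32 (−4.06 ± 0.21). The other largest decreases were mesothelin, Msln (−5.01 ± 0.33, adjusted p = 6.79e-10), Akr1c14 (−4.12 ± 0.27), the dynein Dnah6 (−4.04 ± 0.24) and Ecscr (−3.81 ± 0.21). Increases were led by Igsf10 (4.62 ± 0.30, on chromosome 3), Sh3bgrl (4.48 ± 0.26, adjusted p = 1.84e-10), the hedgehog-binding Hhip (4.0 ± 0.27, on chromosome 8), Evc (3.77 ± 0.35) and the transporter Abcc2 (3.7 ± 0.33). Germline genes were up in 20 and down in 3 of 31 cases (21 up and 3 down adjusted over the list alone, camera adjusted p = 8.98e-05, and adjusted p = 0.633 with an estimated correlation). Sohlh2 was at 3.11 ± 0.19. Lin28b (2.65 ± 0.16) and Ccnd1 (1.72 ± 0.10) rose and the antigen transporter Tap1 (−1.85 ± 0.21) and the immediate early gene Fos (−1.99 ± 0.29) fell. Mitochondrially encoded mRNAs were up in 7 and down in 0 of 13 (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.0259, and adjusted p = 0.857 with an estimated correlation), at 3.26% and 3.38% of the reads. Loop extrusion genes and CTCF partners were up in 11 and down in 2 of 23 (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.0267, and adjusted p = 0.669 with an estimated correlation; 0.0639 without WT ID replicate 1), with Ctcf itself and Patz1 (0.75 ± 0.06, on chromosome 11) among those up. The median of 0.2 was 0.07 after quantile normalization and 0.03 on TPM, a scale that moved the median of all genes by −0.167. Nuclear oxidative phosphorylation genes were up in 15 and down in 1 of 44 (15 up and 1 down adjusted over the list alone, camera adjusted p = 0.0230, and adjusted p = 0.920 with an estimated correlation; 0.0553 without WT ID replicate 1), with a median of 0.15 that was 0.07 after quantile normalization and turned to −0.02 with that move of all genes. Cholesterol synthesis genes were down in 11 and up in 1 of 23 (1 up and 11 down adjusted over the list alone, camera adjusted p = 0.0284, and adjusted p = 0.852 with an estimated correlation; 0.0787 without R448Q ID replicate 2 and 0.103 without WT ID replicate 1). Dhcr7 was at −1.0 ± 0.12. The 8578 calls were 4259 up and 4319 down (996 and 1541 by at least 2-fold), against 2734 up and 6026 down on TPM and 2254 up and 3811 down without chromosomes 1, 3, 8 and 11.

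H455R raised Ptpru, a receptor tyrosine phosphatase (chromosome 4, 131768457 to 131838288), from 53.4 ± 3.15 to 1545 ± 23.1 (log2 fold change 4.83 ± 0.26, adjusted p = 9.33e-10), with increases also in the keratin Krt7 (3.06 ± 0.35), Cd4 (2.84 ± 0.23), Dmkn (2.76 ± 0.30) and the peptidase Klk10 (2.67 ± 0.33). It lowered the potassium channel Kcna2 (−4.65 ± 0.41, adjusted p = 2.32e-07), the epoxide hydrolase Ephx2 (−3.23 ± 0.22), Xlr5b (−2.49 ± 0.36) and the Notch ligand Dll1 (−2.7 ± 0.68; adjusted p up to 0.0978 without WT ID replicate 1). Cell cycle genes fell in 23 and rose in 2 of 34 cases (2 up and 27 down adjusted over the list alone, camera adjusted p = 2.50e-06, and adjusted p = 0.633 with an estimated correlation). The mitotic cyclin Ccnb2 was at −0.46 ± 0.10 and Ccnd1 at 1.14 ± 0.10. Genes of the 2-cell-like state rose in 13 and fell in 0 of 24 (17 up and 0 down adjusted over the list alone, camera adjusted p = 4.51e-05, and adjusted p = 0.652 with an estimated correlation), germline genes likewise in 14 and 0 of 31 (15 up and 4 down adjusted over the list alone, camera adjusted p = 0.00110, and adjusted p = 0.652 with an estimated correlation), and Hox genes in 11 and 0 of 31 (11 up and 0 down adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.486 with an estimated correlation) with Hoxc10 at 1.17 ± 0.22. Among markers of other cell types, neural ectoderm markers had a median of −0.52, with 3 up and 4 down of 11 (3 up and 5 down adjusted over the list alone) and no camera call (adjusted p = 0.264). Fibroblast markers were up in 7 of 10 with 0 down (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.00481, and adjusted p = 0.367 with an estimated correlation), as for Thy1 (1.92 ± 0.27). Mesendoderm markers were up in 6 of 15 with 0 down (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00646, and adjusted p = 0.279 with an estimated correlation), as for Eomes (1.08 ± 0.22). Protocadherins fell in 5 and rose in 0 of 16 (0 up and 5 down adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.633 with an estimated correlation). Pcdhga11 was at −2.06 ± 0.39. Other list calls were lost when 1 library was left out. Cholesterol synthesis genes did so (6 down and 2 up of 23, 2 up and 7 down adjusted over the list alone, camera adjusted p = 0.0368, and adjusted p = 0.857 with an estimated correlation; 0.210 without H455R ID replicate 2 and 0.214 without WT ID replicate 1). Heat shock and unfolded protein genes followed (10 up and 2 down of 24, 10 up and 2 down adjusted over the list alone, camera adjusted p = 0.0421, and adjusted p = 0.872 with an estimated correlation; 0.185 without H455R ID replicate 1 and 0.121 without WT ID replicate 1), then primitive endoderm markers (5 up and 1 down of 12, 6 up and 1 down adjusted over the list alone, camera adjusted p = 0.0421, and adjusted p = 0.498 with an estimated correlation; 0.129 without H455R ID replicate 1 and 0.101 without WT ID replicate 2). Imprinted Mest rose (2.46 ± 0.18) and Usp29 fell (−2.16 ± 0.21). Of 4322 calls 2365 were up and 1957 down (727 and 359 by at least 2-fold), or 1867 up and 1917 down without chromosome 8. Smaller sets of libraries gave 2684 without H455R ID replicate 1, 2564 without WT ID replicate 1 and 2723 without WT ID replicate 2.

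The 2 lines with different substitutions of the same arginine were compared directly, R377C against R377H. Each is 1 line, so line and substitution cannot be told apart here either. Hox genes were higher in R377C in 17 of 31 cases and lower in 0 (18 up and 1 down adjusted over the list alone, camera adjusted p = 2.95e-07, and adjusted p = 0.226 with an estimated correlation). Hoxa2 was at 1.83 ± 0.36 and Hoxc8 at 1.36 ± 0.27. The imprinted Peg10 (chromosome 6, 4747306 to 4760517) was at 2853 ± 1221 in R377C and 384 ± 79.5 in R377H (log2 fold change 2.83 ± 0.29, adjusted p = 1.21e-06), and Peg3 was lower in R377C (−2.11 ± 0.19). Other genes most above R377H were Clca3b (3.36 ± 0.24), Nckap5 (2.45 ± 0.41), Flrt3 (2.37 ± 0.15) and Dio3os (2.28 ± 0.27). Those most below it were Slc5a4b (−2.85 ± 0.42), Mlph (−2.52 ± 0.40), Scml2 (−2.49 ± 0.20), Nxf3 (−2.44 ± 0.17) and Magea8 (−2.51 ± 0.69; adjusted p up to 0.133 without R377C ID replicate 1 or without R377H ID replicate 2). Cholesterol synthesis genes were higher in 10 and lower in 0 of 23 (17 up and 0 down adjusted over the list alone, camera adjusted p = 3.73e-06, and adjusted p = 0.633 with an estimated correlation). Protocadherins were higher in 4 and lower in 0 of 16 (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.00106, and adjusted p = 0.559 with an estimated correlation). Mesendoderm markers were higher in 4 and lower in 0 of 15 (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.00259, and adjusted p = 0.226 with an estimated correlation), the last including Cdx2 (1.95 ± 0.31). Trophectoderm markers were higher in 3 and lower in 0 of 12 (4 up and 0 down adjusted over the list alone, camera adjusted p = 0.0414, and adjusted p = 0.633 with an estimated correlation; 0.0702 without R377C ID replicate 2 and 0.0577 without R377H ID replicate 1). Nuclear oxidative phosphorylation genes were lower in 11 and higher in 0 of 44 (0 up and 14 down adjusted over the list alone, camera adjusted p = 0.00230, and adjusted p = 0.888 with an estimated correlation; 0.0598 without R377C ID replicate 1). Of the 3552 genes called, 1474 were higher and 2078 lower in R377C (479 and 221 by at least 2-fold). The split was 2118 up and 1174 down on TPM and 1462 up and 1287 down without chromosome 11, which was −0.49 relative to the rest. Without 1 library the count was 1856 without R377C ID replicate 1 and 1862 without R377H ID replicate 2.

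**Figure D4:**
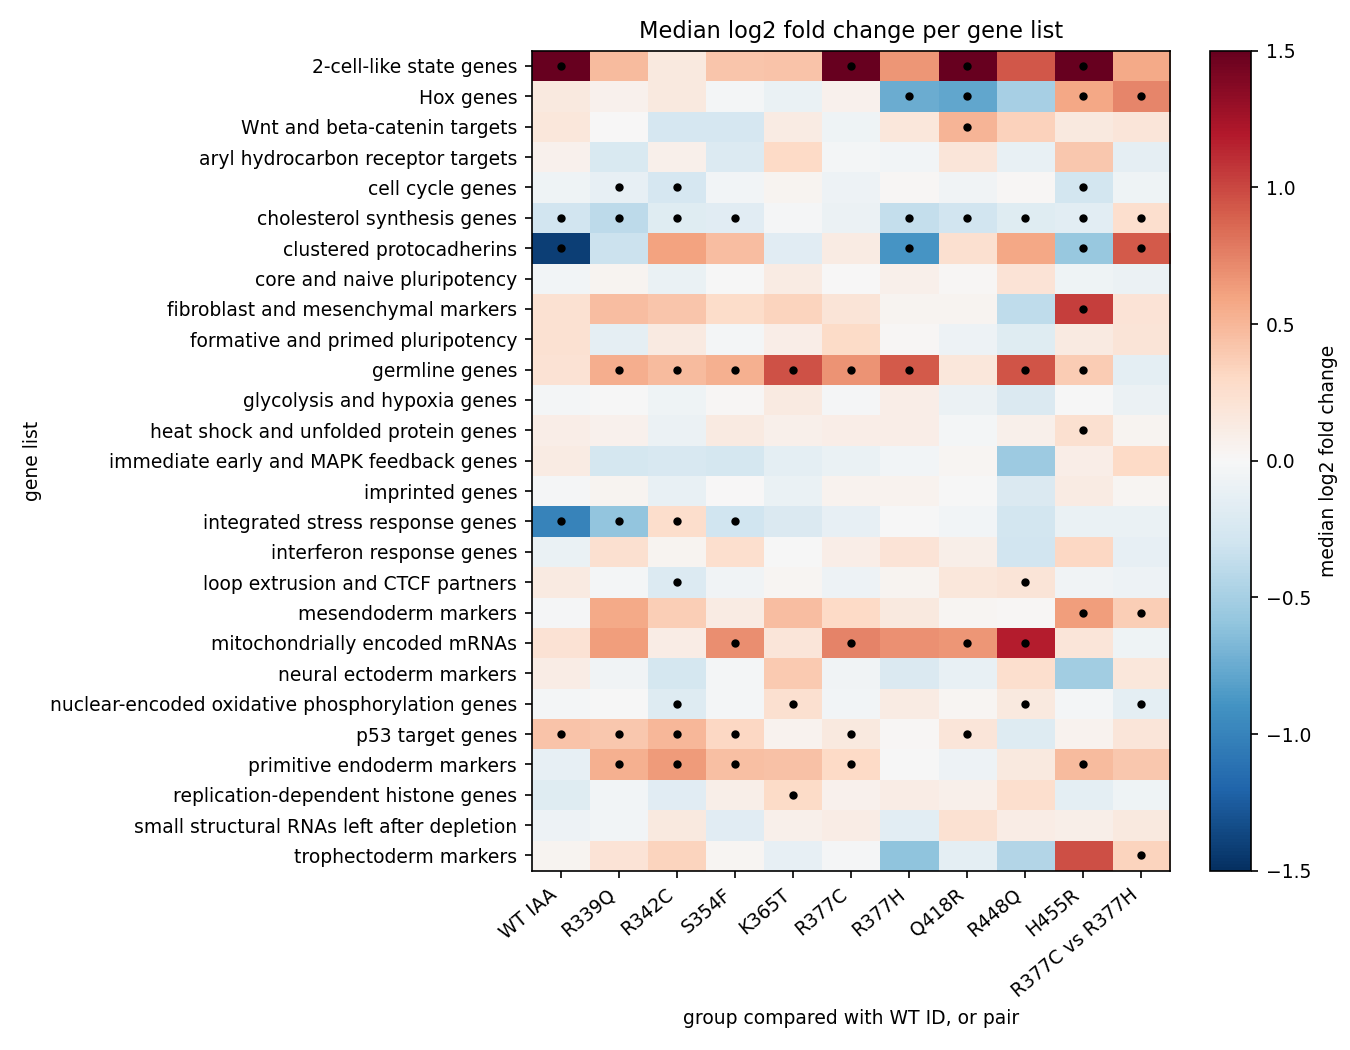
Median log2 fold change of 27 gene lists in 11 comparisons, with colours ending at ±1.5 and a black dot where camera at a preset correlation of 0.01 gave an adjusted p under 0.05. All 64 dotted calls were lost with an estimated correlation.

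The remaining lists gave no camera call in any of the 11 comparisons, although single members changed. Their medians ranged from −0.1 to 0.21 for core and naive pluripotency genes (up to 14 up and 10 down of 30), from −0.18 to 0.29 for formative and primed genes, from −0.22 to 0.13 for glycolysis and hypoxia genes and from −0.55 to 0.3 for immediate early genes. They ranged from −0.22 to 0.12 for imprinted genes, which moved both ways (up to 11 up and 15 down of 38, both in R448Q), from −0.29 to 0.31 for interferon response genes, from −0.52 to 0.39 for neural ectoderm markers and from −0.23 to 0.4 for targets of the aryl hydrocarbon receptor. Small structural RNAs, a sign of how ribosomal depletion and RNA quality differ, had medians from −0.18 to 0.23, with at most 2 of 16 up and 1 down. Their lowest camera adjusted p-values were, in the same order, 0.0630, 0.162, 0.223, 0.0731, 0.174, 0.169, 0.149, 0.345 and 0.374. Of called lists in the other comparisons, medians moved by more than 1.5 times on TPM, beyond the move of all genes, for protocadherins in WT IAA (−1.42 to −0.7) and H455R (−0.57 to −0.29). After quantile normalization others did so, for cell cycle genes in R339Q (−0.12 to −0.08) and, in R377C against R377H, for oxidative phosphorylation (−0.15 to −0.06), mesendoderm (0.36 to 0.24) and trophectoderm markers (0.34 to 0.2). Trophectoderm markers had their highest median in H455R (0.97, 7 of 12 up).

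Genes changed the same way in several mutants were counted next, all 9 comparisons sharing the 2 WT ID libraries. In at least 5 of the 9 mutants 1081 genes rose and 766 fell. At an unadjusted p under 0.05 the counts were 1979 and 1674. Simulated unchanged groups that shared simulated controls gave means of 114 and 115. Each gene varied independently there. A difference of the WT line, or a WT ID deviation shared by many genes, was not modelled. In all 9 mutants 84 rose and 40 fell. Hedgehog-binding Hhip (chromosome 8, 79965851 to 80058006) rose in each, by 0.91 to 4.0 on the log2 scale, and Myh6 (chromosome 14, 54941921 to 54966927) by 1.51 to 2.43. Also up in all 9 were Tmem132d, Tek (chromosome 4, 94739289 to 94874976, 1.27 to 2.80), Raet1d, Rbm44, Brdt, Clip4 (chromosome 17, 71768473 to 71864273, 0.89 to 2.40), H2ac1 and the defensin Defb42. Down in all 9 were Xlr3c (−4.17 to −0.89), Olfr459, Arhgef38 (chromosome 3, 133112278 to 133234949, −3.22 to −1.40), Clca3b, the lysine-degrading enzyme Aass (chromosome 6, 23072173 to 23132986, −3.09 to −1.23), Klhl13 (chromosome X, 23219271 to 23365082), the neurofilament Nefm, Kirrel2, Magea4 and the cardiac troponin Tnni3. In WT IAA these named decreases did not pass, as for Xlr3c (−0.24, limma adjusted p = 0.580), Olfr459 (0.56) and Clca3b (−0.05). Of the named increases, Hhip (−0.26), Raet1d (0.31), Rbm44 (0.44), Clip4 (−0.15) and H2ac1 (0.47) did not pass there, and the others were called up. Against the same WT ID libraries, 43 of the 84 genes up in all 9 mutants were called up in WT IAA. Of the 40 down, 11 were called down. Of the genes up in at least 5 mutants against 1 WT ID library, 25.1% and 24% were called up in WT IAA against the other library (both ways round, chosen after seeing the data), where 4.92% and 5.64% of all genes were. Of those down, 19.2% and 15.3% were called down, where 5.92% and 5.70% of all genes were. Without WT ID replicate 1 the counts were 665 up and 286 down, and without WT ID replicate 2 they were 595 and 412. Against WT IAA in place of WT ID, a choice made after seeing the data, 2291 rose and 1958 fell, of which 459 and 361 were the same genes.

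How far each mutant shared the changes seen with IAA alone was asked from the overlap of calls. R339Q shared the most in total, with 973 genes up in both (219 for independent lists) and 804 down in both (194), and H455R had 777 (236) and 658 (209.6). R448Q shared 746 (424) and 876 (463), K365T 643 (330.0) and 506 (286), Q418R 541 (208) and 600 (277), R377H 528 (269) and 363 (214), S354F 356 (102) and 194 (86.3) and R377C 306 (87.0) and 158 (68.6). R342C shared 352 up (186) and 176 down (267), with 700 genes called in opposite directions against 71 in R339Q. The covariance of log2 fold changes was 0.148 in R339Q, 0.130 in H455R, 0.0852 in R448Q, 0.0817 in Q418R, 0.0746 in K365T, 0.0711 in R377C, 0.0609 in R377H, 0.0572 in S354F and 0.00495 in R342C, where unchanged groups gave 0.0354 to 0.0356. With WT IAA set against 1 WT ID library and the mutant against the other, both ways round and chosen after seeing the data, no control was shared. The covariance was then 0.126 and 0.114 in R339Q, 0.109 and 0.0964 in H455R, 0.0720 and 0.0428 in R448Q, 0.0562 and 0.0515 in Q418R and 0.0469 and 0.0466 in K365T. It was 0.0464 and 0.0401 in R377C, 0.0385 and 0.0277 in R377H, 0.0315 and 0.0274 in S354F and −0.0239 and −0.0219 in R342C. R339Q then shared 743 and 752 genes and R448Q 765 and 677. In R339Q these were 424 and 426 up (69.6 and 75.9 for independent lists). The genes down in both were 319 and 326 (56.1 and 62.9), with 17 and 43 opposite. In R448Q they were 346 and 320 up (164 and 200 for independent lists). There 419 and 357 were down in both (193 and 200), with 289 and 417 opposite. Without WT ID replicate 1 or replicate 2 the genes called the same way in both numbered 923 and 880 in R339Q, 312 and 180 in R342C, 269 and 211 in S354F, 564 and 549 in K365T and 223 and 177 in R377C. In the same order they numbered 424 and 414 in R377H, 573 and 527 in Q418R, 777 and 864 in R448Q and 722 and 710 in H455R.

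Untreated cells, which keep endogenous CTCF and received neither compound, were set beside WT ID. Transgene, compounds and separate deposition coincide in that comparison, so it does not isolate how far the WT transgene restored expression. The deposited tables were scaled separately, so ratios of TPM are given, with a test on recovered reads (edgeR) as an alternative. Glycolysis and hypoxia genes were higher in untreated cells, with a median log2 ratio of 1.18 and 16 of 25 at least 2-fold higher, including the mitophagy receptor Bnip3 (119 and 127 TPM against 9.13 and 7.22) and the aldolase Aldoc (log2 ratio 2.31). The lactate transporter Slc16a3 (4.45), Aire (4.39), Bnip3 (3.90) and the Nodal antagonist Lefty2 (3.36) were highest among single genes. Hox genes were lower (median −1.24, 21 of 31 at least 2-fold), as were mesendoderm markers (−1.28, 8 of 15), germline genes (−0.8, 11 of 31), Wnt targets (−0.78, 6 of 17) and integrated stress response genes (−0.75, 12 of 28). Protocadherins were higher (1.57, 12 of 16), and cholesterol synthesis genes had a median of 0.55 with 20 of 23 higher in both untreated libraries than in either WT ID library. Akr1c14 (−5.91), Dkk1 (−5.65), the aryl hydrocarbon receptor target Cyp1a1 (−5.47), Tpsg1 (−5.17) and Vnn1 (−4.84) were lowest. In WT IAA, Bnip3 (9.82 and 9.83 TPM), Slc16a3 (6.74 and 5.34) and Cyp1a1 (16.4 and 18.6) lay nearer to WT ID than to untreated cells. Such differences do not tell what the transgene restored. Genes called up in WT IAA against the same WT ID libraries had a median log2 change of −0.0562 in untreated cells against WT ID. Those called down had −0.0756. Between untreated cells and WT IAA, edgeR called 8554 genes. In all 2282 genes were at least 2-fold apart with no overlap of the libraries, or 937 with a pseudocount of 1 and 4187 with no filter. Of these 1905 were lower in untreated cells and the rest higher. On recovered reads scaled together, edgeR called 587 higher and 1562 lower by at least 2-fold, or 3649 and 3924 with no fold limit, which was chosen after seeing the data. Libraries of the 2 groups did not overlap for 70.2% of genes, where chance gives 33.3%.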

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

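The tests of R339Q against R342C, of the shared arginine, of few strong genes, of a line difference, and both tests of the stress response were chosen only after the result was seen. Between R377C and R377H, which replace the same arginine, limma called 3552 genes. Hox genes had a median log2 fold change of 0.73 (R377C over R377H), and chromosome 11 was shifted by −0.49. Integrated stress response genes went apart in R339Q and R342C, neighbouring substitutions of finger 3, with a median of −0.86 and 25 of 28 down in R339Q against R342C (camera p = 3.70e-17, adjusted p = 1.00e-15 over 27 lists, adjusted p = 0.802 with an estimated correlation). Without 1 library the p ranged from 2.01e-17 (R342C replicate 1 left out) to 1.21e-13 (R342C replicate 2 left out). Each of these was singled out because 2 lines differed in a direct test of the difference.

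Chromosomes 1, 3 and 8 in R448Q, 11 in R377H and K365T, 8 in H455R and 6 in Q418R were shifted by more than 0.4 on the log2 scale. Each shift is a median over 574 to 1017 genes, which a few strongly changed genes cannot move. At least 82.1% of the measured genes of each lay on the side of its shift. That share was no separate test, because the chromosomes were selected for a large median. Loss of this arginine, shared by R377C and R377H, does not account for chromosome 11 either, as its shift was 0.0528 in R377C against 0.557 in R377H. The third of genes with the lowest means and the third with the highest differed by at most 0.169 (in R448Q 0.447, 0.358 and 0.398 in the lowest against 0.577, 0.527 and 0.536 in the highest, for chromosomes 1, 3 and 8), which is consistent with a changed number of copies of these chromosomes in the lines. No DNA was analysed here, and an effect of CTCF on whole chromosomes was not tested apart from line.

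Among 1081 genes up and 766 down in at least 5 of 9 mutants, 44.4% were called the same way in at least 5 mutants against WT IAA. That argues against a deviation of the 2 shared WT ID libraries as the whole cause, though it may add to it. With genes chosen against 1 WT ID library and changes measured against the other, WT IAA moved in the direction of the mutants by 0.370 and 0.230 of the mutants' median (mean 0.30). A difference between the WT transgene line and the mutant lines cannot be told apart from an effect of the substitutions at that value, because each substitution exists in 1 line.

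Integrated stress response genes were lower in WT IAA than in WT ID by a median of 1.00 on the log2 scale. Doxycycline cannot be told apart from the WT transgene product, since WT ID received both. Among the 9 mutant groups, all given doxycycline, the median of the list medians was −0.124 (R377C), with −0.587 in R339Q, 0.266 in R342C, −0.293 in S354F, −0.221 in K365T, −0.00485 in R377H, −0.0459 in Q418R, −0.271 in R448Q and −0.0983 in H455R, each in a line of its own. Untreated cells, which keep CTCF, had a median of −0.750 relative to WT ID on TPM and of −0.582 on recovered reads scaled together, where edgeR called 20 of 28 down and 1 up. A low level was thus also present with CTCF, but untreated cells received no IAA, so lack of CTCF cannot be told apart from an effect of the compounds.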

How the results depend on the processing

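Local centring, counts without shifted chromosomes, all alternatives for several mutants, left-out libraries for overlaps, gene lists, named genes and chromosomes, scalings for chromosomes, separate WT ID libraries and edgeR without a fold limit were tests chosen only after the result was seen. Counts of called genes for the 11 comparisons stayed within 1.5 times under a pseudocount of 5, no filter, quantile normalization, TPM, edgeR, DESeq2, joint adjustment and local centring. R342C alone moved with only its own groups fitted (2639). The spread then rests on fewer libraries, and other counts went both ways, such as to 5303 in R339Q and 4287 in K365T. By chi-square per gene, which grows with read depth, the libraries of R342C differed most from each other (34.8). R342C replicate 1 was also the deepest library. By the median absolute log2 difference K365T differed most (0.197, against 0.177 in R342C). The cause was not tested. A block for replicate number moved no count by that much. Residuals of same-numbered replicates correlated by −0.248 to 0.382 over 55 pairs of groups (median 0.0230, 10 over 0.1, 7 below −0.1, 0.213 for WT IAA with WT ID). Pairing of some groups is thus not excluded.

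Leaving out 1 library, which lowers the number of samples, gave 1804 to 2537 calls in WT IAA, 1890 to 2833 in R339Q, 2003 to 4189 in R342C, 863 to 1056 in S354F, 4019 to 5556 in K365T and 582 to 905 in R377C. It gave 3016 to 3509 in R377H, 2872 to 3706 in Q418R, 6601 to 7062 in R448Q, 2564 to 3011 in H455R and 1856 to 2655 in R377C against R377H. Genes changed in several mutants ranged from 595 to 665 up and 286 to 412 down, and numbered 2291 and 1958 against WT IAA. Genes shared with WT IAA ranged from 880 to 923 in R339Q, 180 to 312 in R342C, 211 to 269 in S354F, 549 to 564 in K365T, 177 to 223 in R377C, 414 to 424 in R377H, 527 to 573 in Q418R, 777 to 864 in R448Q and 710 to 722 in H455R. With WT IAA against replicate 1 or 2 of WT ID and the mutant against the other they were, in that order, 743 and 752, 190 and 160, 180 and 168, 462 and 464, 146 and 131, 338 and 341, 445 and 439, 765 and 677, and 575 and 575. With at least 2-fold in both they were, in that order, 356, 102, 113, 187, 113, 140, 183, 253 and 293, as that limit requires. List calls ranged from 62 to 82 (64 as reported) and fell to 0 with an estimated correlation. Untreated against WT ID gave 2262 to 2830 genes, 937 with a pseudocount of 1, 4187 with no filter and 7573 with edgeR and no fold limit. The cause was not tested beyond the fewer or additional genes that each limit admits.

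The TPM scale moved the median of all genes by −0.167 in R448Q, 0.100 in R342C, 0.104 in R377C against R377H, −0.0916 in Q418R, −0.0904 in R377H and −0.0775 in K365T, which moves the splits of calls on that scale. Of 1165 called pairs of gene and comparison, 436 were lost in at least 1 left-out setting, 151 with no filter, 116 on TPM, 116 after local centring, 72 after quantile normalization, 62 with only the groups compared, 21 with edgeR, 12 with the block and 11 with a pseudocount of 5. Directions reversed after local centring for Hsph1 in R339Q (0.23) and R377H (0.10), Pds5b in S354F (0.0507), K365T (0.39) and Q418R (0.0109), Ctcf in K365T (−0.00788), Top2a in R377H (−0.0412), Mcm2 (0.17) and Ndufa9 (0.18) in Q418R, Nqo1 in H455R (−0.16) and Sox2 in R448Q (−0.0127). In R377C against R377H they reversed for Stat3 (0.19), Xbp1 (0.0350) and Atp5g1 (0.0484), and without R342C replicate 1 for Cox6c in R342C (0.00415, and −1.0 without R342C replicate 2). Centring removes what neighbouring genes share, and the cause was not tested further. In data simulated with the depths and spread of the 22 libraries, with 200 genes changed in R339Q alone, 38% of those changed 1.5-fold were called.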

Other observations

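Clusters of neighbouring genes fell together in some mutants; the clusters and the tests on them were chosen only after the result was seen. Of 9 Xlr3, Xlr4 and Xlr5 genes (chromosome X, 73074345 to 73292976), all 9 fell in R339Q (median log2 fold change −3.76), R342C (−3.48), S354F (−2.81) and H455R (−2.05), whichever library was left out, and 0 changed in WT IAA. In R377C all 9 fell (−1.89; 7 without R377C replicate 1 and 8 without WT ID replicate 1), in R377H 7 (6 without any 1 library) and in R448Q 7 (5 without R448Q replicate 1 or WT ID replicate 1, 6 without either other library). K365T had 6 (4 without K365T replicate 2, 2 without any other) and Q418R 2 (0 without Q418R replicate 1, 1 without either WT ID library). Near-identical copies share reads, so the members are not independent.

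Among 34 genes from Meg3 to Mirg (chromosome 12, 109541001 to 109749460), 33 fell in S354F (median −3.07, fewer without any 1 library). These neighbours may share transcripts, so the counts may reflect 1 locus. In K365T 27 fell (−1.96, again fewer), 0 changed in WT IAA, R339Q, R342C, R377C or Q418R, and 2 rose in H455R (again fewer). R377H had 14 (18 and 1 without R377H replicate 1 and 2, 8 and 7 without WT ID replicate 1 and 2), and R448Q had 16 (9 without either R448Q library, 12 and 5 without WT ID replicate 1 and 2). Of 11 genes from Ascl2 to Phlda2 (chromosome 7, 142966829 to 143503150), 10 fell and 1 rose in R448Q, with 9 falling without R448Q replicate 1 and 10 without any other library. In R377H 9 fell (median −1.56; 9 and 8 without R377H replicate 1 and 2, 7 and 8 without WT ID replicate 1 and 2), and in K365T 6 (4 without any 1 library). Elsewhere 1 fell in WT IAA and 2 each in S354F and R377C, 2 rose in R342C and 1 in Q418R (each 0 to 1 when 1 library was left out), and 0 changed in R339Q or H455R (1 fell in H455R without WT ID replicate 2). The gene that rose was the noncoding Kcnq1ot1, named after its value was seen (1.47 ± 0.26).

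Integrated stress response medians per library, on TPM relative to WT ID, were −0.94 and −1.03 in WT IAA, −0.64 and −0.93 in untreated cells, −0.67 and −0.47 in R339Q, −0.38 and −0.48 in R448Q, −0.52 and −0.13 in K365T, −0.15 and −0.38 in S354F, and 0.34 and 0.41 in R342C. They were −0.10 and −0.17 in Q418R, −0.14 and −0.08 in R377H, −0.16 and −0.04 in R377C, −0.01 and −0.11 in H455R, and 0.10 and −0.10 in WT ID. The first principal component held 23.2% of the variance, the second 16% and the third 11.8%.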
